A study of Mus musculus with 12 samples.

How the data were processed

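Total RNA from mouse lungs was hybridised to 12 Affymetrix Murine Genome 430A arrays, 3 in each of 4 groups formed by Nrf2 genotype (wild type or knockout) and breathing (spontaneous, or mechanical at a high tidal volume). The deposited values are probe set signals in units of intensity, which the submitters' processing notes credit to the Affymetrix GeneChip Operating Software, version 1.4; detection calls and p-values of that software were not used here. The design text describes a scaling of every array to an average of 500, but the deposited intensity values do not show it, because the trimmed means of the arrays range from 73.9 to 446 in all but 1 array, which is higher still. The values are linear, and every array ends near the same highest signal, between 12046 and 14272, so very bright probe sets may be compressed by the scanner's ceiling. Replicates are not stated to be separate animals, so every p-value measures the spread between these samples, which may be technical.

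Because the scaling was missing, each array was multiplied so that its mean signal, trimmed by 2% at each end, became 500, and the 12 arrays were then quantile normalized. This step was chosen after the values had been seen and before any test was run; the scaling alone, equal medians, and the deposited values without any scaling were run as alternatives. A pseudocount of 16 was added before taking log2, which pulls the fold changes of weak signals towards 0. Probe sets starting with AFFX (64 controls) were left out, and a probe set was kept when its scaled signal reached 100 on at least 3 arrays. Gene names came from the platform's annotation, which names 1 gene for 20393 probe sets, several genes for 691 and no gene for 1555. Of the single-gene probe sets, 20364 had their Entrez Gene identifier in the RefSeq annotation of assembly GRCm38.p6, which changed 0 symbols. Each gene was represented by its probe set with the highest mean log2 signal, which left 9294 genes from 14510 probe sets. Probe sets whose names end in s_at or x_at can also bind related transcripts, so a value for a gene of a large family, such as Gstm1, can include its paralogs.

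Group means were fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with eBayes and an intensity trend, 8 residual degrees of freedom and 4.44 prior degrees of freedom. The 7 contrasts were the effect of ventilation in each genotype, the effect of genotype under each kind of breathing, the interaction between genotype and ventilation, and the 2 averages. P-values were adjusted by the method of Benjamini and Hochberg over the 9294 genes within a contrast, and a gene was called at an adjusted p under 0.05. All tests were two-sided. The median standard error of a log2 difference was 0.231 between 2 groups, 0.327 for the interaction and 0.164 for an average, and the number of arrays limits the precision. An exact permutation of 3 arrays against 3 cannot go below p = 0.1, so no exact test could pass the threshold for a comparison of 2 groups.

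The comparisons, the threshold, the filter, the pseudocount, the gene lists and the rule for naming genes were fixed before the data were examined. The rule took Nfe2l2, the 12 largest rises and the 12 largest falls among called genes whose groups did not overlap, and up to 4 passing members of each list (or 2 with the smallest p, as values, where none passed). Where fewer than 5 genes were called, it took the 5 with the smallest p. There were 30 lists, which held 424 entries, of which 332 were measured. They cover NRF2 target genes, stress and inflammatory responses, functions of the alveolar barrier, and markers of lung, blood and neighbouring tissues such as heart, fat and thymus. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 30 lists within a contrast. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in one direction without comparing them with other genes, were the planned checks. For the 2 averaged contrasts, an exact stratified permutation of the mean list score per array, with a smallest possible p of 0.005, was added later. Counts of list members are given over all genes tested and adjusted over the list alone.

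In simulated data with the same groups and each gene's own spread, 100 genes were given a log2 change of 1 and 100 a change of 2. The fit called 57% of the first and 87% of the second in the wild-type ventilation contrast. The shares were 23% and 72% for the interaction and 80% and 99% for the averaged genotype contrast, with 4 to 10 false calls per contrast. A raised list was called in 7 of 7 simulated contrasts and 0 of 203 unchanged lists were. Genes were drawn independently there and no array stood apart. The simulation therefore does not show how the list test behaves with correlated genes or an outlying array. Y-linked genes were expressed on every array (Eif2s3y from 510.2 to 1177.1), so no fit with sex as a covariate was made. Alternatives covered the filter, pseudocount, scaling, trend, array weights, choice of arrays, choice of probe sets, threshold, a block on the replicate number, a covariate for RNA quality (the log2 ratio of the 3' to the 5' probe sets of the beta-actin control) and leaving out each array in turn. The covariate, the unscaled values and the lists without 1 array were added after the data had been seen.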

Results

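Lungs of CD-1/ICR mice with and without Nrf2 were profiled after 2 h of breathing. Nrf2, encoded by Nfe2l2, is the transcription factor that switches on antioxidant and detoxifying genes. In each genotype, 3 arrays came from mice breathing on their own (SpV, the controls) and 3 from mice on a ventilator set to a tidal volume of 30 ml/kg (HVT), which overstretches the lung. The title of the study links oxidative stress to injury of the lung by ventilators. The comparisons ask what ventilation changes in each genotype, what the loss of Nrf2 changes under each kind of breathing, and whether the response to ventilation depends on Nrf2. The labels give whole lung for wild-type SpV array 1 and the left lobe for the other 11. Values below are log2 differences of normalized signal ± SE from limma with n = 3 arrays per group, and group means are normalized signals ± SD.

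The arrays differed in brightness and in RNA quality. The trimmed mean signal before normalization was 363 ± 54.9 (SD) in the wild-type SpV group, 386 ± 92.5 in wild-type HVT, 329.8 ± 222 in knockout SpV and 207 ± 34.5 in knockout HVT. Knockout SpV array 1 stood apart at 73.9, with a 3' to 5' ratio of the beta-actin controls of 8.76 against 1.39 to 3.10 in the other 11 arrays. Its mean correlation with the other arrays was 0.874 against 0.922 to 0.943. The 3 knockout HVT arrays had actin ratios of 3.10, 2.21 and 3.02, above the 1.99, 1.58 and 1.53 of the wild-type HVT arrays. Without scaling the median gene differs by -0.48 between the genotypes at rest, -0.80 after ventilation and -0.63 averaged over both. It differs by -0.30 with ventilation in the knockout, 0.01 in the wild type and -0.14 averaged over genotypes, and by -0.33 in the interaction. Values called unscaled below are to be read against those shifts.

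**Figure D1:**
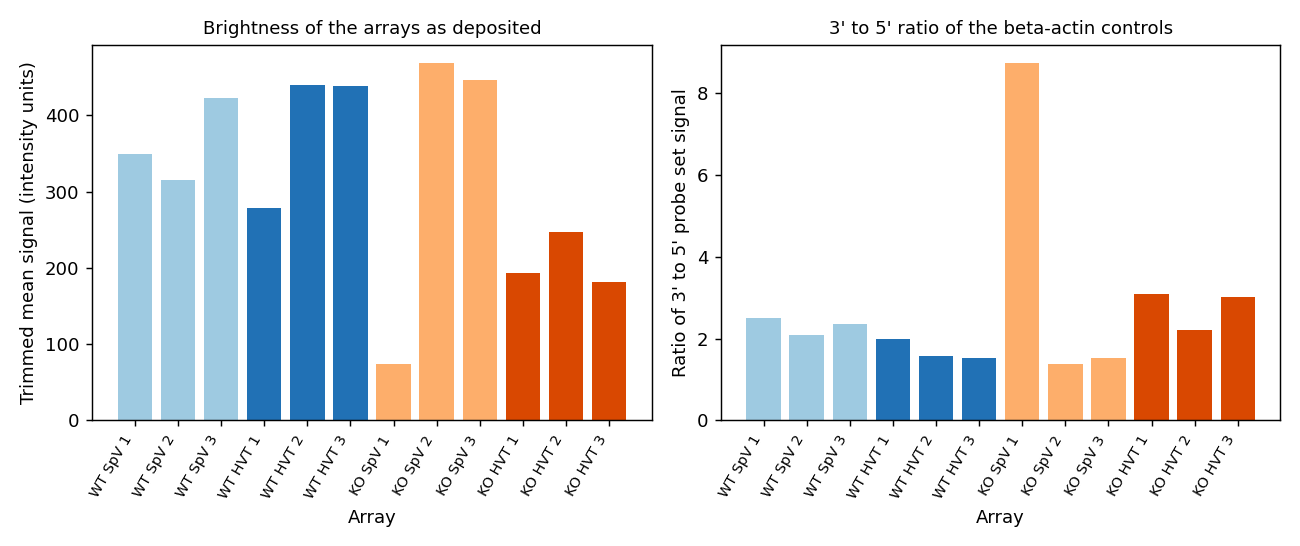
The left panel plots the trimmed mean signal of each deposited array in intensity units and the right panel the 3' to 5' signal ratio of the beta-actin control probe sets, with 1 bar per array coloured by group (WT or KO for genotype, SpV or HVT for breathing). Knockout SpV array 1 has the lowest signal, 73.9, and the highest ratio, 8.76.

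Nfe2l2 itself separated the genotypes on every array. Its signal lay between 2144.3 and 3298.2 on the 6 wild-type arrays and between 36.2 and 61.3 on the 6 knockout arrays. The log2 difference was -5.55 ± 0.20 in SpV lungs (adjusted p = 1.38e-08) and -5.54 ± 0.20 in HVT lungs (adjusted p = 1.42e-08). The labels do not say which part of the gene was deleted.

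In wild-type lungs, 2 h of ventilation raised 7 genes, from 2.07-fold for Bmx to 6.06-fold for Noct. Maff, a small MAF transcription factor that pairs with NRF2 and other partners, rose from 213 ± 66.2 to 1193.6 ± 135 (SD, n = 3), a log2 change of 2.44 ± 0.22 (adjusted p = 0.000884). Mt1, a metal-binding metallothionein, rose from 1387.1 ± 299.9 to 6716.9 ± 1913.4, a log2 change of 2.25 ± 0.25 (adjusted p = 0.00495). Noct, a rhythmic NADP(H) phosphatase, rose by 2.60 ± 0.39, and Fos, a subunit of the AP-1 transcription factor, by 2.42 ± 0.37, from 886.6 ± 101.3 to 4860.5 ± 1081.9. Arid5a, which stabilises Il6 mRNA, rose by 1.70 ± 0.24, Eppk1, a keratin-binding cytolinker, by 1.61 ± 0.25 and the tyrosine kinase Bmx by 1.05 ± 0.16, each of these and of Noct and Fos at adjusted p = 0.0295. For all 7 genes, the 3 ventilated arrays lay above the 3 control arrays, an arrangement that chance gives to 10% of genes and that 17.1% of all genes showed in 1 direction or the other.

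Groups of related genes moved with them in wild-type lungs. All 21 measured immediate early genes were higher after ventilation, with a median log2 change of 1.33. Among them 2 passed over all genes and 12 when adjusted over the list alone, and the list was called (camera adjusted p = 1.05e-20, adjusted p = 0.158 with an estimated correlation). Members that did not pass over all genes had values of 2.04 ± 0.47 for Egr1 and 1.25 ± 0.32 for Zfp36, which destabilises cytokine mRNAs. Acute cytokines and chemokines had a median of 0.98 with 6 of 7 members higher, 0 passing and 2 adjusted over the list alone (camera adjusted p = 0.00126, adjusted p = 0.228 with an estimated correlation). Ptgs2, the inducible prostaglandin synthase, had a value of 2.87 ± 0.63 and Il6 2.45 ± 0.78. The cytokine median was 0.44 without wild-type HVT array 3 and 0.61 without knockout HVT array 3. NF-kB feedback and adhesion genes were higher for 12 of 14 members at a median of 0.19, with 1 member adjusted over the list alone (camera adjusted p = 0.00297, adjusted p = 0.239 with an estimated correlation). That median was 0.11 without wild-type SpV array 1 and 0.33 without SpV array 3. The metallothionein and glucocorticoid list was called at a median of 0.58, with 1 member passing and 2 adjusted over the list alone (camera adjusted p = 0.000212, adjusted p = 0.239 with an estimated correlation). Mt2 had a value of 2.13 ± 0.36. With the actin ratio as a covariate the metallothionein median was 0.25, still called, and the NF-kB call ended, at 0.22.

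The Nrf2 target list was also higher after ventilation of wild-type lungs, by a median of 0.25. Of its members, 24 of 30 were higher, 0 passed over all genes and 2 did adjusted over the list alone (camera adjusted p = 4.56e-06, adjusted p = 0.198 with an estimated correlation). The median was 0.38 without wild-type HVT array 2 and 0.17 without HVT array 3. The members with the smallest p had values of 1.17 ± 0.21 for Srxn1, which reactivates oxidised peroxiredoxins, and 0.90 ± 0.23 for Gclc, the rate-limiting enzyme of glutathione synthesis. Smooth muscle markers had a median of 0.18 with 1 member adjusted over the list alone, a call lost without wild-type HVT array 1, where the median was 0.09, and with the actin ratio as a covariate, at 0.23 (camera adjusted p = 0.0148, adjusted p = 0.3 with an estimated correlation). Red cell and erythroid genes were lower, at a median of -1.22 with 4 of 4 lower and 3 adjusted over the list alone (camera adjusted p = 0.000212, adjusted p = 0.114 with an estimated correlation). Fibroblast and mesothelial markers were lower too, at -0.59 with 8 of 9 lower and 3 adjusted over the list alone (camera adjusted p = 0.00119, adjusted p = 0.292 with an estimated correlation), and at -0.39 without wild-type HVT array 1. Slc4a1, the anion exchanger of red cells, had a value of -1.70 ± 0.34, and Col1a1, Col1a2 and Col3a1 had -1.05 ± 0.32, -0.68 ± 0.17 and -0.70 ± 0.20. Endothelial markers, with 13 of 13 lower at a median of -0.45 (camera adjusted p = 0.00119), and heat shock genes, with 12 of 15 lower at -0.26 (camera adjusted p = 0.000819), had 0 members passing. Each of these lists had adjusted p = 0.425 with an estimated correlation, and the endothelial median was -0.77 without wild-type HVT array 2.

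In this comparison limma called 7 genes, all higher, among 745 with an unadjusted p under 0.05 (464.7 by chance), and fry called 1 of the 30 lists, the red cell genes (adjusted p = 0.0245). Maff and Mt1 kept their calls whichever array was left out, and the other 5 in 4 to 6 of the 12 fits that left 1 out. The count was 3 without wild-type SpV array 1, 2 without SpV array 2 or 3, 2 without HVT array 1, 17 without HVT array 2, and 3 without HVT array 3. It was 45 without knockout SpV array 1, 2 without knockout HVT array 2, and 0 on the deposited values without scaling.

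**Figure D2:**
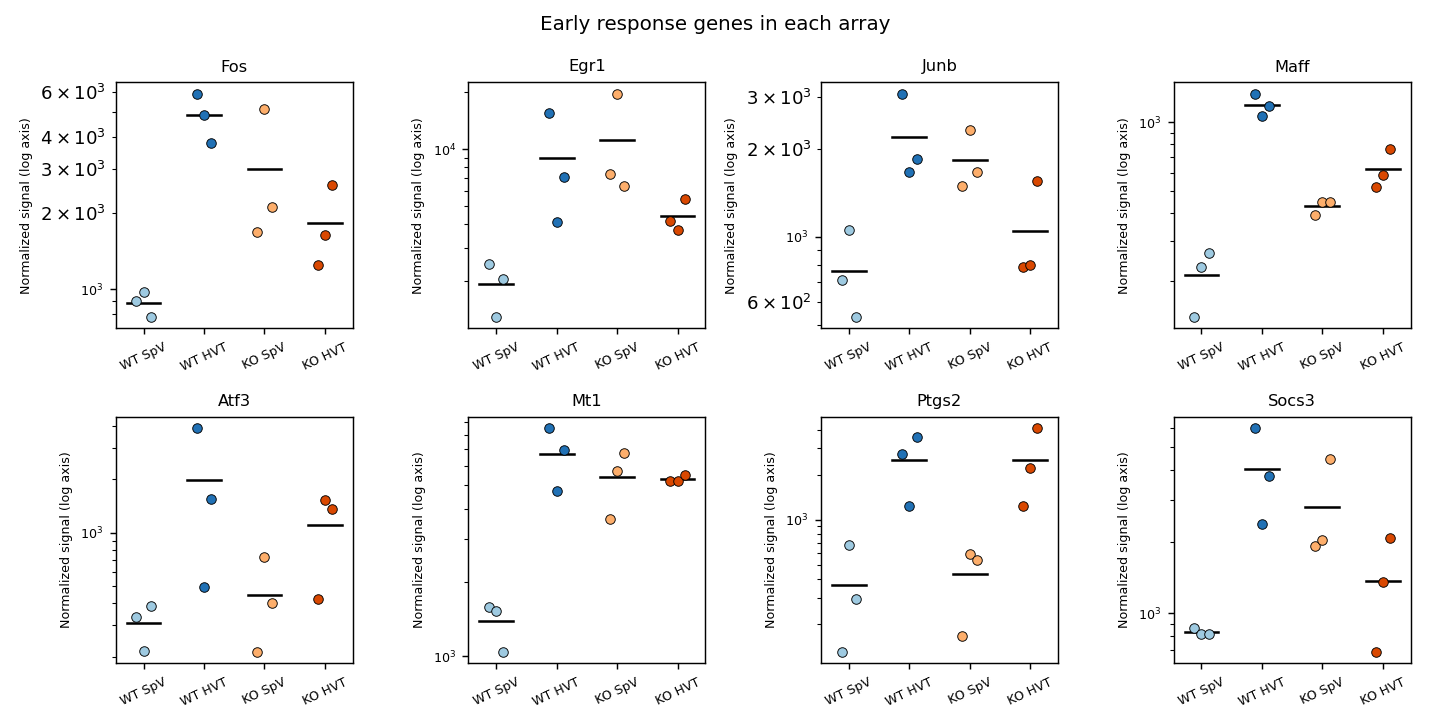
Normalized signal on a log axis for 8 early response genes on each of the 12 arrays, with 1 point per array, arrays grouped by genotype (WT or KO) and breathing (SpV or HVT), and a line at the mean of each group. Fos lies between 778.1 and 978.7 in the wild-type SpV group and between 3770.5 and 5934.2 in the wild-type HVT group.

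In knockout lungs no single gene passed after ventilation, while markers of neutrophils, alveolar type I cells and endothelium were lower as lists. The 5 genes with the smallest p, each at adjusted p = 0.202, follow. Cebpa, a myeloid and epithelial transcription factor, had a value of -0.78 ± 0.13 and Atp1b1, a subunit of the sodium pump, 0.79 ± 0.15. The lipolysis inhibitor G0s2 had -1.16 ± 0.22, the neutrophil calprotectin subunit S100a8 -2.50 ± 0.47 and the lectin-like receptor Klra17 -1.19 ± 0.23. Neutrophil markers had a median of -1.43 with 9 of 10 lower, 0 passing and 8 adjusted over the list alone (camera adjusted p = 5.68e-09, adjusted p = 0.254 with an estimated correlation, fry adjusted p = 0.0486). S100a8 averaged 5934.4 ± 4281.9 in knockout SpV and 852.4 ± 79.9 in knockout HVT lungs, against 2972.7 ± 506.7 and 2619.4 ± 1501.8 in wild type. Heat shock genes had a median of -0.61 with 12 of 15 lower and 7 adjusted over the list alone (camera adjusted p = 9.59e-07, adjusted p = 0.422 with an estimated correlation). Hspa1b had a value of -2.96 ± 0.64 and Dnaja1 -1.03 ± 0.22.

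Alveolar type I markers had a median of -0.65 with 7 of 8 lower and 1 adjusted over the list alone (camera adjusted p = 0.000856, adjusted p = 0.688 with an estimated correlation). The water channel Aqp5 had a value of -0.71 ± 0.19. Endothelial markers had -0.67 with 12 of 13 lower and 1 adjusted over the list alone (camera adjusted p = 0.00265, adjusted p = 0.696 with an estimated correlation), a call lost without knockout SpV array 2, where the median was -0.26. It was -1.42 without knockout SpV array 1 and -0.44 without array 3. NF-kB genes had -0.33 with 14 of 14 lower, and -0.64 without knockout SpV array 1 (camera adjusted p = 0.00265, adjusted p = 0.375 with an estimated correlation). T and NK markers had -0.51 (camera adjusted p = 0.0383, adjusted p = 0.375 with an estimated correlation), lost without knockout SpV array 2, at -0.25, or knockout HVT array 2, at -0.52. Heart muscle markers were higher for 13 of 13 members at 0.30, with 1 adjusted over the list alone (camera adjusted p = 0.00587, adjusted p = 0.753 with an estimated correlation). This call was lost without knockout SpV array 1, at 0.21, or knockout HVT array 2, at 0.19, and the median was 0.45 without knockout SpV array 3. The endothelial and type I marker scores were lowest on the arrays with actin ratios of 2.21 or more among the knockouts. Relative to the mean of all arrays, knockout SpV array 1 had -1.09 and -0.88. The 3 knockout HVT arrays had -0.62, -0.72 and -0.97 for endothelium and -0.63, -0.90 and -0.53 for type I cells. The wild type did not follow this. Wild-type SpV arrays 1 and 3, with ratios of 2.51 and 2.36, had 0.51 and 0.76 for endothelium and 0.38 and 0.43 for type I cells. The low-scoring knockout arrays were also the dimmest before normalization. Their trimmed means were 73.9 for SpV array 1 and 194, 247 and 182 for the HVT arrays, against 279 or more elsewhere. Brightness as a source was not tested.

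Here limma called 0 genes, with 987 at an unadjusted p under 0.05, and fry called 1 of the 30 lists. This count depends on knockout SpV array 1. Without it 600 genes were called, 205 higher and 395 lower. Among them were S100a8 at -3.04 ± 0.36, the collagenase Mmp8 at -2.80 ± 0.33, the receptor Ager of type I cells at -1.61 ± 0.23, the endothelial kinase receptor Tek at -1.59 ± 0.23 and Ttpa, which transfers vitamin E, at 2.33 ± 0.27. Then 7 of 10 neutrophil, 6 of 8 type I and 6 of 13 endothelial markers fell, at medians of -1.80, -0.90 and -1.42, with adjusted p = 0.126, 0.205 and 0.286 with an estimated correlation. The 2 knockout SpV arrays that remain had trimmed means of 446 or more, against 182 to 247 in the knockout HVT arrays. Without knockout HVT array 1 the count was 3.

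At rest, lungs without Nrf2 had less of several detoxifying enzymes. Aox1, an aldehyde oxidase, fell by 1.93 ± 0.16 on the log2 scale, from 1467.3 ± 88.5 to 374.4 ± 37.4 (adjusted p = 0.000123). The glutathione transferases Gstm1 and Gsta3 had -1.62 ± 0.17 (adjusted p = 0.000819) and -1.84 ± 0.25 (adjusted p = 0.0065). The carboxylesterases Ces1g and Ces1f had log2 differences of -3.38 ± 0.41 (adjusted p = 0.00235) and -3.29 ± 0.35 (adjusted p = 0.000819). The splicing factor Cwc22 fell by 1.95 ± 0.21 (adjusted p = 0.000819), and Car4, a carbonic anhydrase of lung capillaries, had a value of -1.89 ± 0.27 (adjusted p = 0.00791). The endosomal SNARE Vamp3 rose by 1.62 ± 0.14, from 1791.3 ± 89.1 to 5550 ± 708.7 (adjusted p = 0.000158), and Mt1 by 1.92 ± 0.25 (adjusted p = 0.00583). The groups did not overlap for any of the 31 called genes, an arrangement that 18.4% of all genes showed in this comparison.

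Other called genes at rest included Pigr, which carries IgA across epithelium, at 1.64 ± 0.24 (adjusted p = 0.00811), the platelet chemokine Ppbp at 1.91 ± 0.31 (adjusted p = 0.0202) and the TNF-induced Tnfaip2 at 1.85 ± 0.33 (adjusted p = 0.0345). Also called were the lipid droplet protein Cidea at 1.65 ± 0.25 (adjusted p = 0.0115), the smooth muscle calponin Cnn1 at 1.19 ± 0.18 (adjusted p = 0.0136) and the cardiac myosin-binding protein Mybpc3 at 1.31 ± 0.23 (adjusted p = 0.0366). Lower were the splicing factor Usp39 at -3.26 ± 0.49 (adjusted p = 0.0115) and Tfpi, which inhibits tissue factor, at -1.05 ± 0.17 (adjusted p = 0.0202). Cwc22, Tfpi, Mybpc3 and Metap1d, which rose by 1.53 ± 0.26 (adjusted p = 0.0242), are among the 100 measured genes nearest to Nfe2l2 in the GRCm38.p6 annotation. Of the 25 called genes named by the rule, 9 kept their calls in all 12 fits that left out 1 array: Nfe2l2, Ces1g, Ces1f, Cwc22, Aox1, Mt1, Gsta3, Vamp3 and Gstm1.

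The Nrf2 target list was lower at rest in the knockout, with 25 of 30 members lower at a median of -0.32. Over all genes 4 members passed (Aox1, Gstm1, Ces1g and Gsta3), with 8 lower and 1 higher adjusted over the list alone (camera adjusted p = 2.06e-07, adjusted p = 0.151 with an estimated correlation, fry adjusted p = 0.0113). NF-kB genes were higher, at a median of 0.63 with 1 passing and 6 adjusted over the list alone (camera adjusted p = 0.000146, adjusted p = 0.151 with an estimated correlation, fry adjusted p = 0.0441). Smooth muscle markers were higher at 0.46 with 1 passing and 6 adjusted over the list alone (camera adjusted p = 0.000159, adjusted p = 0.151 with an estimated correlation, fry adjusted p = 0.027). Heart muscle markers were higher at 0.64 with 1 passing and 5 adjusted over the list alone (camera adjusted p = 1.42e-05, adjusted p = 0.351 with an estimated correlation), and at 0.42 without wild-type SpV array 3. Endothelial markers were lower in 13 of 13 cases at -0.95, with 9 adjusted over the list alone (camera adjusted p = 1.11e-05, adjusted p = 0.319 with an estimated correlation). Cdh5, the cadherin of endothelial junctions, had a value of -1.87 ± 0.53. The endothelial median was -0.50 and Cdh5 had -1.06 without knockout SpV array 1, the dim array with an actin ratio of 8.76. That array had an endothelial score of -1.09, against 0.43 and 0.11 on the other 2 knockout controls.

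The remaining calls at rest depended on single arrays. Immediate early genes had a median of 0.50 with 4 adjusted over the list alone (camera adjusted p = 0.000426, adjusted p = 0.463 with an estimated correlation), and Egr1 had a value of 2.38 ± 0.47. Acute cytokines had 0.87 (camera adjusted p = 0.0105, adjusted p = 0.319 with an estimated correlation) and neutrophil markers 0.72 with 2 adjusted over the list alone (camera adjusted p = 0.00283, adjusted p = 0.351 with an estimated correlation). Without knockout SpV array 2 these 3 calls were lost, at medians of 0.37, 0.61 and 0.23. The immediate early median was 0.88 and the neutrophil median 1.29 without knockout SpV array 1. The endoplasmic reticulum stress list, at 0.30 but -0.20 on the unscaled values, was also lost without knockout SpV array 2, at 0.23, and had 0.18 without wild-type SpV array 3 (camera adjusted p = 0.0176, adjusted p = 0.151 with an estimated correlation, fry adjusted p = 0.0441). Type I markers, at -0.49 (camera adjusted p = 0.0018, adjusted p = 0.443 with an estimated correlation), were lost without knockout SpV array 1, at -0.17, and had -0.80 without array 2. Also lost without array 1 were ciliated cell markers, at 0.42 but -0.05 on the unscaled values (camera adjusted p = 0.00397, adjusted p = 0.406 with an estimated correlation), and fibroblast markers, at -0.56 (camera adjusted p = 0.0094, adjusted p = 0.378 with an estimated correlation), which had 0.25 and 0.0017 without it. The fibroblast median was -0.91 without knockout SpV array 3. Heat shock genes had 0.26, but -0.21 on the unscaled values (camera adjusted p = 0.0298, adjusted p = 0.607 with an estimated correlation). They lost the call without wild-type SpV array 1 or 2, at 0.18 and 0.14, or knockout SpV array 2 or 3, at 0.03 and 0.23.

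In this comparison limma called 31 genes, 15 higher and 16 lower, with 1279 at an unadjusted p under 0.05, and fry called 5 of 30 lists. The count was 18 without wild-type SpV array 1, 11 without array 2 and 14 without array 3, 173 without knockout SpV array 1, 16 without knockout SpV array 3, and 6, all lower, on the unscaled values.

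After ventilation, knockout lungs had less of several antioxidant enzymes than ventilated wild-type lungs. Srxn1 had 829.7 ± 195 in wild-type HVT and 165.3 ± 16.3 in knockout HVT lungs, a log2 difference of -2.20 ± 0.21 (adjusted p = 0.000212). Gpx2, a glutathione peroxidase of epithelia, fell by 2.19 ± 0.29 (adjusted p = 0.00422), and Gclc fell by 1.35 ± 0.23 (adjusted p = 0.0201). The thioredoxin reductase Txnrd1 fell by 1.54 ± 0.27 (adjusted p = 0.0257) and the carbonyl reductase Cbr3 fell by 1.42 ± 0.27 (adjusted p = 0.0336). The quinone reductase Nqo1 fell from 214.2 ± 22.8 to 72.7 ± 20.1 (SD, adjusted p = 0.0419). Gstm1 had -2.00 ± 0.17, Gsta3 -1.97 ± 0.25, Aox1 -1.99 ± 0.16 and Ces1g -3.88 ± 0.41 (adjusted p = 0.000119, 0.00312, 8.64e-05 and 0.000592). Of the 30 measured Nrf2 targets, 28 were lower at a median of -0.57, 10 passed and 18 did when adjusted over the list alone. This was the 1 list of this comparison whose call held with an estimated correlation (camera adjusted p = 1.26e-19, adjusted p = 0.0205 with an estimated correlation, fry adjusted p = 0.000306).

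**Figure D3:**
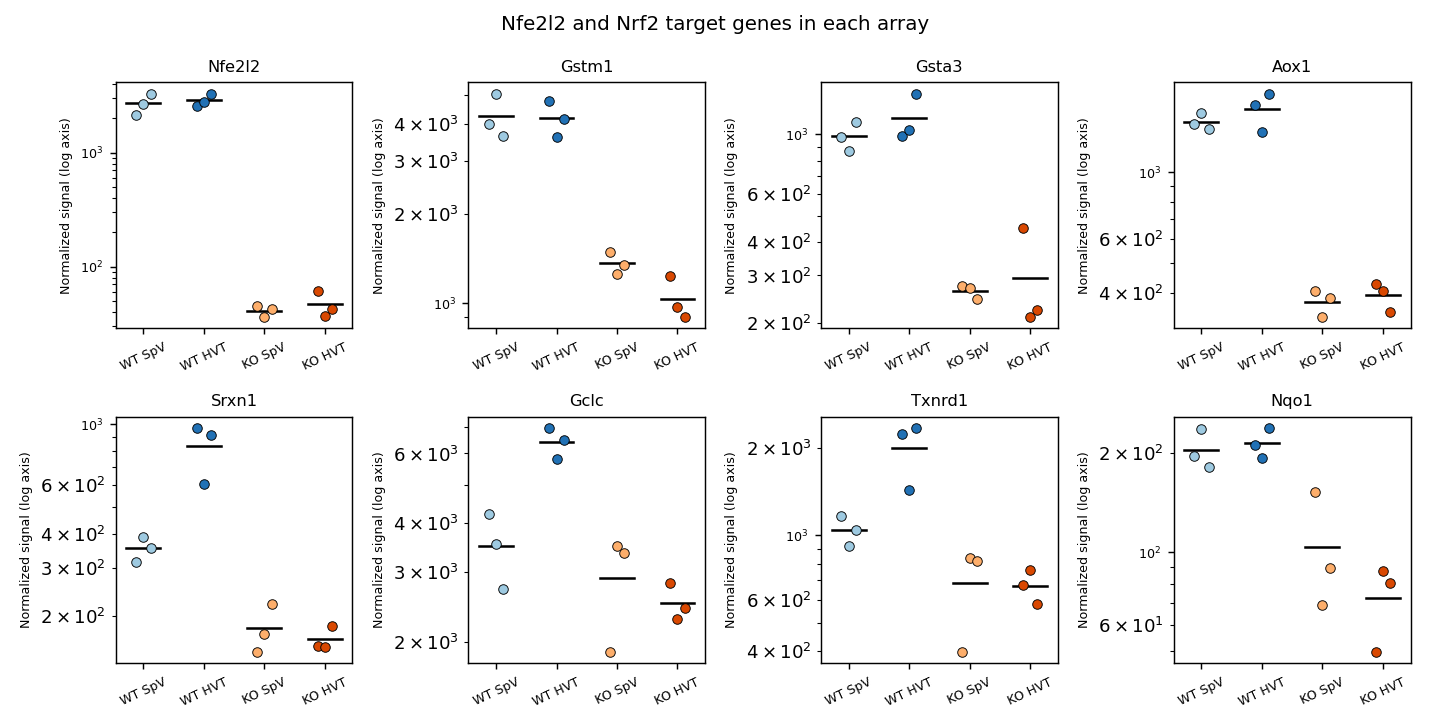
Normalized signal on a log axis for Nfe2l2 and 7 Nrf2 target genes on each of the 12 arrays, with 1 point per array, arrays grouped by genotype (WT or KO) and breathing (SpV or HVT), and a line at the mean of each group. Srxn1 lies between 606.4 and 966.3 in the wild-type HVT group and between 155.2 and 184 in the knockout HVT group.

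The called genes with the largest rises in ventilated knockout lungs were Bpifa1, Reg3g, Ltf and Rd3, and genes of heart and other striated muscle were also called. Bpifa1, a secreted airway surface protein, had 253.4 ± 279.8 in wild-type and 6942 ± 5297.2 in knockout HVT lungs (4.96 ± 0.73, adjusted p = 0.00982), a call lost without wild-type HVT array 2. Lactoferrin, Ltf, rose by 2.80 ± 0.41 (adjusted p = 0.00982), lost without wild-type HVT array 1 or 2, and the antibacterial lectin Reg3g by 3.96 ± 0.78 (adjusted p = 0.0419), kept in 3 of 12 fits. Rd3, known from photoreceptors, rose by 2.25 ± 0.44 (adjusted p = 0.0401), kept in 2 of the 9 fits that measured it. It did not pass the signal filter when a knockout HVT array was left out, so it was measured only through the group where it is higher. Scgb3a1, a club cell secretoglobin, rose by 0.94 ± 0.19 (adjusted p = 0.0482), kept in 2 of 12 fits. The muscle genes Mybpc3, Smpx, Ttn, Sln and Tnnt2 rose by 1.59 ± 0.23, 1.77 ± 0.28, 1.64 ± 0.30, 1.60 ± 0.31 and 1.13 ± 0.21 (adjusted p = 0.00982, 0.0158, 0.0276, 0.0379 and 0.0341). They kept their calls in 10, 9, 7, 5 and 5 of the 12 fits in turn. Heart muscle markers were higher for 13 of 13 members at a median of 1.10, with 7 passing and 11 adjusted over the list alone (camera adjusted p = 1.21e-14, adjusted p = 0.196 with an estimated correlation, fry adjusted p = 0.0147). Within groups their signals went up and down together from array to array at a mean correlation of 0.569. Cwc22 fell by 2.38 ± 0.21 (adjusted p = 0.000119), and Klf2, a transcription factor induced by flow in endothelium, fell by 1.99 ± 0.41 (adjusted p = 0.0468). Plaur, the urokinase receptor, fell by 1.18 ± 0.21 (adjusted p = 0.0248). Klf2 kept its call in 3 and Plaur in 7 of the 12 fits.

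Early response genes were lower in ventilated knockout than in ventilated wild-type lungs. Of the immediate early genes 21 of 21 were lower at a median of -0.88, with Klf2 passing and 8 adjusted over the list alone (camera adjusted p = 2.92e-09, adjusted p = 0.339 with an estimated correlation). Fos had a value of -1.45 ± 0.37. Type I markers were lower in 8 of 8 cases at -0.85, with 7 adjusted over the list alone (camera adjusted p = 7.86e-07, adjusted p = 0.339 with an estimated correlation). Endothelial markers were lower in 12 of 13 at -1.06, with 7 adjusted over the list alone (camera adjusted p = 2.09e-06, adjusted p = 0.339 with an estimated correlation). Ager and Cdh5 had values of -1.58 ± 0.48 and -2.05 ± 0.53, and the knockout HVT arrays had the higher actin ratios given above. That ratio as a covariate brought the endothelial median to -0.65 and the type I median to -0.61, with both lists still called. Within groups the ratio varies mostly through knockout SpV array 1, so this fit cannot decide on RNA quality as a source. Genes of ion and water transport had -0.47 with 4 lower adjusted over the list alone (camera adjusted p = 0.0185, adjusted p = 0.196 with an estimated correlation, fry adjusted p = 0.0147), lost without knockout HVT array 1, at -0.27. The interferon list had 0.79, but -0.06 on the unscaled values (camera adjusted p = 0.0016, adjusted p = 0.496 with an estimated correlation), and was lost without knockout HVT array 3, at 0.15.

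The other called lists after ventilation were each lost without some array. With the actin ratio as a covariate the calls of ciliated cell, club cell and extracellular matrix genes also ended, at 0.24, 0.024 and -0.088, while B cell markers had 0.56. B cell markers had 0.37 (-0.34 on the unscaled values, 0.29 without wild-type HVT array 2 and 0.39 without knockout HVT array 1, camera adjusted p = 0.00719, adjusted p = 0.496 with an estimated correlation). Ciliated cell markers had 0.48 (-0.36 on the unscaled values, 0.22 and 0.36 without those arrays, camera adjusted p = 0.0104, adjusted p = 0.496 with an estimated correlation). Club cell markers had 0.10 with 1 passing and 2 adjusted over the list alone (-0.12 on the unscaled values, 0.06 and 0.09 without those arrays, camera adjusted p = 0.0353, adjusted p = 0.512 with an estimated correlation). Smooth muscle markers had 0.34 (-0.54 on the unscaled values, 0.24 without wild-type HVT array 3 and 0.18 without knockout HVT array 1, camera adjusted p = 0.0185, adjusted p = 0.371 with an estimated correlation). Extracellular matrix genes had -0.23 with 2 adjusted over the list alone (-0.19 without wild-type HVT array 1 and -0.37 and -0.43 without knockout HVT arrays 1 and 2, the latter still called, camera adjusted p = 0.0317, adjusted p = 0.496 with an estimated correlation).

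Coagulation genes had -0.51 with Plaur passing, and 4 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0428, adjusted p = 0.496 with an estimated correlation). The actin covariate ended this call, at -0.34, and that of the neutrophil markers, at -0.58. The call was lost without wild-type HVT array 2, at -0.35, or 3, at -0.56, and without knockout HVT array 1, at -0.54, or 2, at -0.44. Neutrophil markers had -0.66 although the member that passed, Ltf, was higher, and 1 other was lower when adjusted over the list alone (camera adjusted p = 0.0491, adjusted p = 0.512 with an estimated correlation). That call was lost without wild-type HVT array 1, at -0.72, or 2, at -0.43, knockout SpV array 3, at -0.66, and knockout HVT array 1, at -0.69, or 2, at -0.63. Cell cycle genes had 0.32, but -0.40 on the unscaled values (camera adjusted p = 0.0483, adjusted p = 0.436 with an estimated correlation), a call kept in 5 of the 12 fits. It was lost without knockout SpV array 1, 2 or 3, at 0.33, 0.32 and 0.32, wild-type SpV array 2, at 0.32, wild-type HVT array 3, at 0.26, and knockout HVT array 1 or 3, at 0.27 and 0.34.

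In this comparison limma called 69 genes, 31 higher and 38 lower, with 1192 at an unadjusted p under 0.05, and fry called 3 of 30 lists. The count was 43 without wild-type SpV array 1, 45 without SpV array 3, and 19, 16 and 45 without wild-type HVT arrays 1, 2 and 3. It was 485 without knockout SpV array 1, 44 without knockout SpV array 3, 42, 18 and 17 without knockout HVT arrays 1, 2 and 3, and 29 (4 higher and 25 lower) on the unscaled values. Across the comparisons at rest and after ventilation, 14 genes were called in both, all in the same direction. If the calls were independent, 0.23 would be called in both. They are not fully independent, since both comparisons use the same estimate of each gene's spread.

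Whether the response to ventilation depended on Nrf2 was tested by the interaction. Early response genes differed between the genotypes as lists. Of the immediate early genes 20 of 21 had a lower response in the knockout, at a median of -1.39, with 0 passing over all genes and 12 adjusted over the list alone (camera adjusted p = 1.32e-19, adjusted p = 0.145 with an estimated correlation). The values were -3.20 ± 0.67 for Egr1, -3.01 ± 0.52 for Fos (adjusted p = 0.221), -2.34 ± 0.46 for Junb and -1.94 ± 0.32 for Maff (adjusted p = 0.199). Group means of Fos were 886.6 ± 101.3 and 4860.5 ± 1081.9 in wild-type SpV and HVT lungs, and 2977.2 ± 1885.2 and 1826.8 ± 692.1 in knockout SpV and HVT lungs. Mt1 had an interaction of -2.22 ± 0.36 (adjusted p = 0.199), Socs3, a feedback inhibitor of cytokine signalling, -3.19 ± 0.59 (adjusted p = 0.255) and Bmx -1.22 ± 0.23. The Nrf2 target list had -0.26 with 24 of 30 lower and 1, Srxn1, adjusted over the list alone (-1.28 ± 0.29; camera adjusted p = 2.77e-06, adjusted p = 0.145 with an estimated correlation).

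Of the other lists, NF-kB genes had an interaction of -0.61 with 2 adjusted over the list alone (camera adjusted p = 1.83e-07, adjusted p = 0.118 with an estimated correlation). Acute cytokines had -1.13 with 7 of 7 lower (camera adjusted p = 0.00124, adjusted p = 0.145 with an estimated correlation). Their median was -0.65 and -0.51 without wild-type HVT arrays 1 and 3 and -0.69 without knockout HVT array 1. The NF-kB median was -0.99 without knockout SpV array 1. Neutrophil markers had -1.34 with 3 adjusted over the list alone (camera adjusted p = 3.36e-06, adjusted p = 0.145 with an estimated correlation). For S100a8 and Mmp8 the values were -2.19 ± 0.66 and -2.18 ± 0.76. Heart muscle markers had 0.36 with 13 of 13 higher (camera adjusted p = 5.63e-05, adjusted p = 0.453 with an estimated correlation), and 0.64 and 0.55 without wild-type HVT array 3 and knockout HVT array 3. The endoplasmic reticulum stress, metallothionein, interferon and fibroblast lists were also called. The actin covariate ended the calls of the first 2, at -0.30 and -0.12, and moved the fibroblast median from 0.31 to 0.69. On the unscaled values the fibroblast median was -0.13, above the -0.33 of the median gene. None of these 4 lists held with an estimated correlation (camera adjusted p = 0.145, 0.453, 0.453 and 0.453) or in every fit that left out 1 array.

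Over all genes limma called 0 for the interaction, with 452 at an unadjusted p under 0.05 (464.7 by chance) and a smallest adjusted p of 0.199; fry called 0 of the 30 lists (smallest adjusted p = 0.22). Without knockout SpV array 1 the count was 82, 11 higher and 71 lower. Called then were Mt1 at -2.44 ± 0.30 (adjusted p = 0.0129), Fos at -3.31 ± 0.46 (adjusted p = 0.0142) and the neutrophil chemokine Cxcl1 at -4.18 ± 0.63 (adjusted p = 0.0142), with the heme oxygenase Hmox1 at -2.29 ± 0.39 (adjusted p = 0.0285) and Gclc at -1.32 ± 0.23 (adjusted p = 0.0287). Then the NF-kB and metallothionein lists, at medians of -0.99 and -0.87, each had adjusted p = 0.0166 with an estimated correlation. With all arrays no gene could be called for ventilation in both genotypes, since 0 were called in the knockout. An unadjusted p under 0.05 in both was found for 169 genes, 159 of them in the same direction. Independent comparisons would give 79.1, but these share the estimate of each gene's spread. Without knockout SpV array 1, 6 genes were called in both in the same direction. Across genes, which are not independent replicates, the 2 ventilation effects correlated at r = 0.276.

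**Figure D4:**
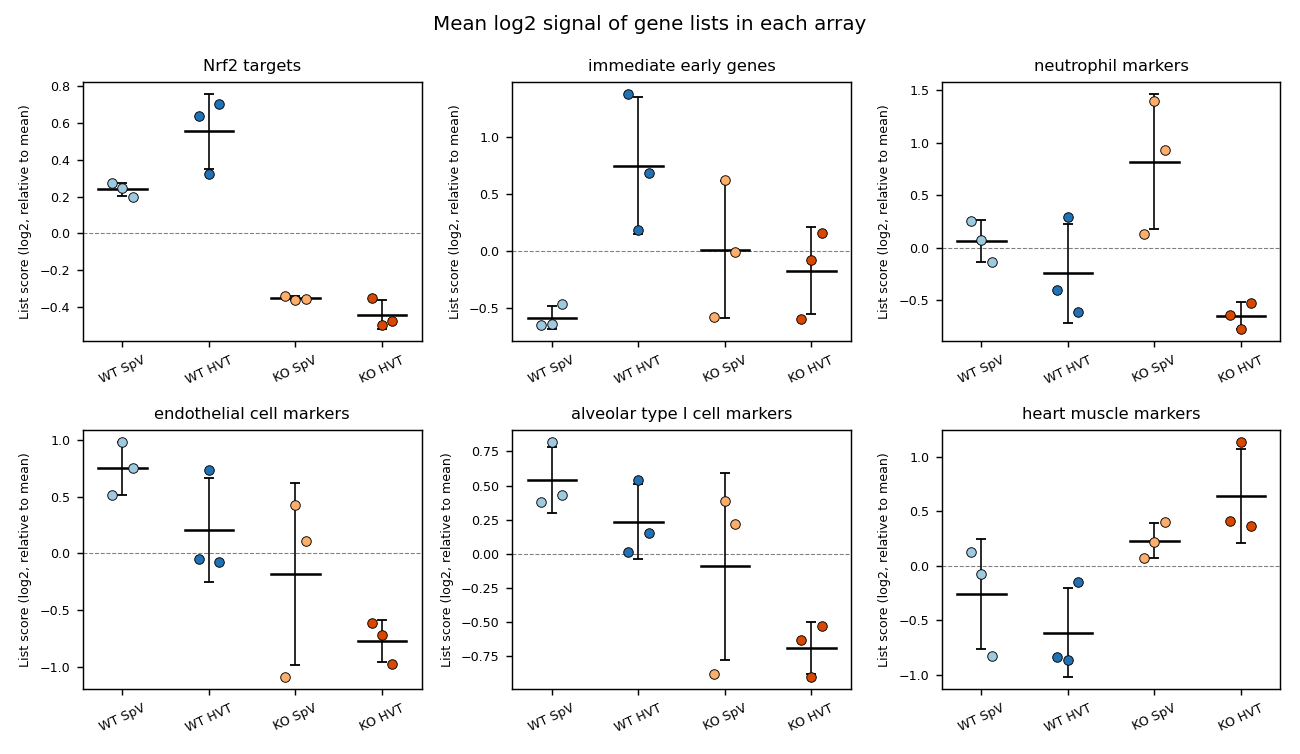
Mean log2 signal of 6 gene lists on each of the 12 arrays, relative to the mean over all arrays. Each point is an array, lines are group means and bars are 1 SD (n = 3 arrays). The Nrf2 target score lies between 0.20 and 0.70 on the wild-type arrays and between -0.50 and -0.34 on the knockout arrays.

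Averaged over the genotypes, ventilation raised Maff by 1.47 ± 0.16 (adjusted p = 0.0052), the call that held whichever array was left out. Ptgs2 rose by 2.69 ± 0.44 (adjusted p = 0.0437), from 365.9 ± 277.2 to 2506.5 ± 1184.2 in wild-type and from 430 ± 228.9 to 2510.9 ± 1446.2 in knockout lungs. Ttpa rose by 1.76 ± 0.25 (adjusted p = 0.0371), Atp1b1 by 0.66 ± 0.10 and Mt1 by 1.14 ± 0.18 (each at adjusted p = 0.0388). In the knockout the Mt1 signals overlapped, at 3630.6 to 6771 in SpV and 5188 to 5510 in HVT lungs. Whether its response differs between the genotypes is not settled, since its interaction did not pass (limma adjusted p = 0.199). Slc4a1 fell by 1.62 ± 0.24 (adjusted p = 0.0382) and Plekho1, a signalling adaptor, fell by 0.67 ± 0.11 (adjusted p = 0.0437). These 6 kept their calls in 2 to 5 of the 12 fits that left out 1 array. Heat shock genes were lower for 14 of 15 members at a median of -0.44, with 8 adjusted over the list alone (camera adjusted p = 1.61e-06), and neutrophil markers at -0.87 with 6 adjusted over the list alone (4.48e-06). Also lower were endothelial markers at -0.54 (9.19e-05), type I markers at -0.39 (0.00102) and red cell genes at -0.81 with Slc4a1 passing and 3 adjusted over the list alone (0.000836). Immediate early genes were higher at 0.52 with 1 passing and 4 adjusted over the list alone (4.48e-06). With an estimated correlation, adjusted p = 0.46, 0.378, 0.46, 0.46, 0.205 and 0.46 for these lists in turn. The endothelial median was -0.85 and the immediate early median 0.27 without knockout SpV array 1.

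The metallothionein list, at 0.30 with Mt1 passing, was lost without knockout SpV array 1, at 0.13 (camera adjusted p = 0.00448, adjusted p = 0.46 with an estimated correlation). It had 0.18 without wild-type HVT array 1, 0.49 without knockout SpV array 2 and 0.17 with the actin covariate. T and NK markers, at -0.38 (camera adjusted p = 0.0413, adjusted p = 0.382 with an estimated correlation), kept the call in 7 of 12 fits. They lost it without wild-type SpV array 1 or 3, at -0.40 and -0.36, wild-type HVT array 1, at -0.37, knockout SpV array 2, at -0.31, and knockout HVT array 2, at -0.33. The Nrf2 targets, at 0.11 (camera adjusted p = 0.0481, adjusted p = 0.46 with an estimated correlation), kept it in 5. They lost it without wild-type SpV array 2 or 3, at 0.12 and 0.11, wild-type HVT array 1 or 3, at 0.11 and 0.07, knockout SpV array 2 or 3, at 0.11 and 0.10, and knockout HVT array 1, at 0.09. In an exact stratified permutation of list scores 0 of the 30 lists passed (smallest adjusted p = 0.15), and fry called 1, the red cell genes (adjusted p = 0.0116).

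For this average limma called 10 genes, 7 higher and 3 lower, with 1236 at an unadjusted p under 0.05. The count was 1 without wild-type SpV array 1 or 3, wild-type HVT array 1 or 3, or knockout HVT array 2 or 3. It was 20 without wild-type HVT array 2, 647 without knockout SpV array 1, 2 without knockout SpV array 2, 4 without knockout HVT array 1, 21 (12 higher and 9 lower) with the scaling alone and 2 on the unscaled values. The SpV and HVT arrays did not overlap for 6 of the 10 called genes, and for 1.12% of all genes.

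Averaged over both kinds of breathing, 348 genes differed between knockout and wild-type lungs. The Nrf2 targets were lower for 28 of 30 members at a median of -0.50, with 14 passing, and 18 lower and 2 higher adjusted over the list alone (camera adjusted p = 1.33e-14, adjusted p = 0.0519 with an estimated correlation, exact permutation adjusted p = 0.03). Aox1 fell by 1.96 ± 0.11 (adjusted p = 1.72e-06) and Gstm1 fell by 1.81 ± 0.12 (adjusted p = 5.06e-06). Ces1g fell by 3.63 ± 0.29 (adjusted p = 2.49e-05) and Srxn1 fell by 1.56 ± 0.15 (adjusted p = 0.000123). Bpifa1 rose by 4.28 ± 0.51 and Ltf by 2.41 ± 0.29 (each at adjusted p = 0.00108), and Pigr by 1.36 ± 0.17 (adjusted p = 0.00125). Ppbp rose by 1.76 ± 0.22 (adjusted p = 0.00133) and Vamp3 by 1.56 ± 0.10 (adjusted p = 4.16e-06). Car4 fell by 1.84 ± 0.19 (adjusted p = 0.000314), Igfbp2, which binds insulin-like growth factors, fell by 2.28 ± 0.43 (adjusted p = 0.0153) and Cdh5 fell by 1.96 ± 0.37 (adjusted p = 0.0168). Each gene named in this paragraph except Srxn1, which those fits did not follow in this contrast, kept its call in all 12 fits that left out 1 array.

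Endothelial markers were lower for 12 of 13 members at -0.85, with 4 passing and 10 adjusted over the list alone (camera adjusted p = 1.97e-07, adjusted p = 0.291 with an estimated correlation, exact permutation adjusted p = 0.03). Type I markers were lower for 8 of 8 at -0.67, with 4 passing and 8 adjusted over the list alone (camera adjusted p = 3.53e-06, adjusted p = 0.336 with an estimated correlation, exact permutation adjusted p = 0.0429). The 4 knockout arrays with actin ratios of 2.21 or more had endothelial scores of -1.09, -0.62, -0.72 and -0.97, against 0.43 and 0.11 on the other 2 knockout arrays. These 4 are knockout SpV array 1 and the whole knockout HVT group. Wild-type SpV arrays 1 and 3, with ratios of 2.51 and 2.36, had endothelial scores of 0.51 and 0.76. A high ratio therefore did not go with a low score on every array. The same 4 knockout arrays were also the dimmest before normalization, with trimmed means of 73.9, 194, 247 and 182. The lowest of the other arrays was 279, on wild-type HVT array 1. Brightness as a source of the low scores was not tested, and it cannot be told apart from them here. With the actin ratio as a covariate both lists were still called, at -0.79 and -0.49. That ratio varies within groups mostly through knockout SpV array 1, so the covariate cannot decide on RNA quality for these lists. Ager fell by 1.36 ± 0.34 (adjusted p = 0.0481) and Pdpn, podoplanin, fell by 0.80 ± 0.18 (adjusted p = 0.03), with calls kept in 3 and 4 of 12 fits. Heart muscle markers were higher for 13 of 13 at 0.83, with 10 passing and 11 adjusted over the list alone (camera adjusted p = 2.61e-11, adjusted p = 0.212 with an estimated correlation, exact permutation adjusted p = 0.0429). Among them were Mybpc3 at 1.45 ± 0.17 (adjusted p = 0.000775), Tnnt2 at 0.99 ± 0.15 (adjusted p = 0.00576) and Myh6 at 0.78 ± 0.12 (adjusted p = 0.00628). Smooth muscle markers were higher at 0.40, with 3 passing and 6 adjusted over the list alone (camera adjusted p = 0.00058, adjusted p = 0.212 with an estimated correlation, exact permutation adjusted p = 0.03). On the unscaled values they had -0.23, above the -0.63 of the median gene. Ciliated cell markers were higher at 0.49, with Rsph1 passing at 1.02 ± 0.22 (camera adjusted p = 0.00197, adjusted p = 0.436 with an estimated correlation, exact permutation adjusted p = 0.03). Unscaled, the ciliated cell markers had -0.21, also above the -0.63 of the median gene. Their median was 0.33 without knockout SpV array 1 and 0.32 with the actin covariate. Ion and water transport genes were lower at -0.48, with 3 passing and 7 adjusted over the list alone (camera adjusted p = 0.0306, adjusted p = 0.212 with an estimated correlation, exact permutation adjusted p = 0.03). This call was lost without wild-type SpV array 1, at -0.41, or knockout HVT array 1, at -0.31.

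B cell markers were higher for 9 of 9 members at 0.40, with Ighm, the heavy chain of IgM, passing at 1.71 ± 0.34 (adjusted p = 0.0188). On the unscaled values the B cell list had -0.18, above the -0.63 of the median gene. The list had camera adjusted p = 0.0222, adjusted p = 0.62 with an estimated correlation and exact permutation adjusted p = 0.165. That list lost its call without wild-type SpV array 2, at 0.16, wild-type HVT array 2, at 0.18, knockout SpV array 2, at 0.35, or knockout HVT array 1, at 0.31. In the coagulation list, which was not called (median -0.41, camera adjusted p = 0.218), Procr, the endothelial protein C receptor, rose by 0.72 ± 0.13 (adjusted p = 0.0113). Thbd, thrombomodulin, fell by 1.71 ± 0.43 (adjusted p = 0.045), with the call kept in 3 of 12 fits.

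For this average limma called 348 genes, 149 higher and 199 lower, with 1986 at an unadjusted p under 0.05, and the exact permutation called 7 and fry 6 of the 30 lists. The count was 199, 171 and 139 without wild-type SpV arrays 1, 2 and 3, and 208 and 122 without wild-type HVT arrays 1 and 2. It was 625 without knockout SpV array 1, 580 without knockout SpV array 2, 178, 216 and 181 without knockout HVT arrays 1, 2 and 3, and 118 (4 higher and 114 lower) on the unscaled values. Without knockout SpV array 1, 344 of the 348 calls were kept. Of the 348 genes, 133 have several probe sets, and for 105 of these all probe sets went in the same direction. The knockout and wild-type arrays did not overlap for 160 of the 348, and for 2.53% of all genes.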

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

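The comparison with other divisions of the arrays was planned; the tests of the heart muscle and immediate early patterns were chosen only after the result was seen. Of the lists, 10 were called for the interaction, so their response to ventilation differed between the genotypes at the preset correlation. The medians were -0.26 for Nrf2 targets, -1.13 for acute cytokines, -1.39 for immediate early genes, -0.61 for NF-kB genes, -0.29 for endoplasmic reticulum stress, -0.38 for metallothionein and glucocorticoid genes, 0.78 for interferon genes, 0.31 for fibroblast markers, -1.34 for neutrophil markers and 0.36 for heart muscle markers. With an estimated correlation 0 of the 10 passed (smallest adjusted p = 0.118), nor did any with fry (smallest adjusted p = 0.22), and limma called 0 single genes, with 452 at an unadjusted p under 0.05.

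Several of these lists rest on single arrays. The interferon list lost its call without knockout SpV array 1, at 0.69, or knockout HVT array 3, at 0.33, and had 1.23 without knockout HVT array 2. On the unscaled values the fibroblast list had -0.13, above the -0.33 of the median gene. It lost its call without knockout SpV array 1, at -0.18, or knockout HVT array 2, at 0.40. Its median was 0.56 without wild-type SpV array 2, 0.16 and 0.67 without wild-type HVT arrays 1 and 2, 0.63 and 0.68 without knockout SpV arrays 2 and 3, and 0.17 and 0.51 without knockout HVT arrays 1 and 3. Endoplasmic reticulum stress genes lost it without wild-type SpV array 3, at -0.27, wild-type HVT array 2, at -0.30, knockout SpV array 2, at -0.29, or knockout HVT array 3, at -0.22. Metallothionein genes lost it without wild-type SpV array 3, at -0.43, wild-type HVT array 2, at -0.27, knockout SpV array 2 or 3, at -0.26 and -0.20, or knockout HVT array 1 or 3, at -0.43 and -0.41. They had -0.65 without wild-type SpV array 2, -0.87 without knockout SpV array 1 and -0.59 without knockout HVT array 2. With the actin ratio as a covariate the calls of the metallothionein and endoplasmic reticulum stress lists ended, at -0.12 and -0.30, and the fibroblast median was 0.69. Calls that held but moved were those of acute cytokines (-0.65 and -0.51 without wild-type HVT arrays 1 and 3, -0.69 without knockout HVT array 1), NF-kB genes (-0.99 without knockout SpV array 1) and heart muscle markers (0.64 and 0.55 without wild-type HVT array 3 and knockout HVT array 3).

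Immediate early genes had a lower response to ventilation in the knockout at the preset correlation, by a median of -1.39, with 0 of 21 members passing in limma (12 adjusted over the list alone), adjusted p = 0.145 with an estimated correlation and 0.22 with fry. Without knockout SpV array 1 the median was -1.58, with 7 of 21 members passing, which argues against that array as the whole source. With the actin ratio as a covariate the median was -1.17. Within groups that ratio varies mostly through knockout SpV array 1, at 8.76 against 1.39 and 1.52 on the other knockout controls. The covariate therefore cannot decide on RNA quality as a source. The knockout controls already had a median 0.50 above the wild-type controls, while the ventilated knockouts had -0.88. Whether that higher starting point alone makes the difference stays open, since the comparison of the ventilated groups had p = 0.0631 in limma's camera with an estimated correlation. Handling of the control animals before the lungs were taken may also act on Fos and Egr1, and was not tested.

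Heart muscle markers were higher in the knockout, by a median of 0.83 with 10 of 13 members passing. Within groups their signals deviate together from array to array with a mean correlation of 0.569, where 1000 random lists of like signal had a median of -0.002 and a highest value of 0.449. A differing amount of heart tissue or of cardiac muscle around the pulmonary veins taken with the lungs may lie behind Tnnt2, Myh6 and Mybpc3. The random lists were matched by signal only, and markers of the same tissue can vary together whatever the reason. The correlation therefore does not decide between this and a change of the muscle in the knockout. Mean Tnnt2 signals were 3962.1, 3692.3, 7025.2 and 7871.5 in wild-type SpV and HVT and knockout SpV and HVT lungs. With the actin ratio as a covariate 11 of 13 markers still passed, at a median of 0.82. As above, that ratio varies within groups mostly through knockout SpV array 1, so this fit cannot decide on RNA quality. The whole lung used for wild-type SpV array 1 is not the source, since its heart score of 0.13 was the highest of the wild-type arrays and the list was called in all 12 fits that left out 1 array, at 0.74 to 0.92. A change of the muscle in the knockout itself stays open.

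Other divisions of the same arrays show what the counts are worth. For 3 arrays against 3 the 10 divisions are too few for a share under 0.05: the real counts were 7 for ventilation of wild-type lungs (highest other 0; 1 of 10 gave as many), 0 for ventilation of knockout lungs (highest other 1; 10 of 10, with 987 genes at an unadjusted p under 0.05 in limma), 31 for genotype at rest (highest other 1; 1 of 10) and 69 for genotype after ventilation (highest other 0; 1 of 10). For genotype averaged over breathing, 1 of 100 drawn divisions, the real one, gave as many as 348 (highest other 2), which argues against chance. For ventilation averaged over genotypes 1 of 100, the real one, gave as many as 10 (highest other 5). This is the smallest share that 100 divisions can give, so chance is made less likely for that count but not excluded. The count does not hold up to changes, since it was 1 without wild-type SpV array 1 or 3, wild-type HVT array 1 or 3, or knockout HVT array 2 or 3, and 1 without the filter or the trend, and the exact permutation called 0 lists (smallest adjusted p = 0.15). For the interaction, 100 of 100 gave at least the real count of 0 and the highest other gave 7, so that count does not stand apart from chance.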

How the results depend on the processing

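The actin covariate and the unscaled values were tests chosen only after the values were seen. Counts are given for ventilation in wild type, ventilation in knockout, genotype at rest, genotype after ventilation, interaction, averaged ventilation and averaged genotype, in which the main values were 7, 0, 31, 69, 0, 10 and 348. Array weights gave 431, 1423, 1433, 549, 173, 1559 and 1478, with 94 genes shared by the ventilation contrasts. The weights of knockout SpV arrays 1, 2 and 3 were 0.127, 1.15 and 4.68. The weighted mean of that group therefore rests mostly on array 3. The actin ratio as covariate gave 71, 54, 386, 139, 1, 506 and 674, with 6 shared. Averaged ventilation gave 1 without the filter, 1 without the trend, 21 with the scaling alone, 20 with every probe set and 111 at an adjusted p under 0.10. Ventilation in wild type gave 4 without the trend, 19 with only the groups compared, 11 at 0.10 and 0 on the unscaled values. Genotype at rest gave 12 with only the groups compared, 80 with every probe set, 82 at 0.10 and 6 on the unscaled values; genotype after ventilation gave 165, 104, 125 and 29. Averaged ventilation gave 2 and averaged genotype 118 on the unscaled values, and averaged genotype 754 at 0.10. For ventilation in knockout and the interaction, the other settings apart from leaving out arrays, array weights and the covariate gave 0 in limma where they were run (the interaction was not run with only the groups compared). At the main settings 987 and 452 genes had an unadjusted p under 0.05.

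Leaving out 1 array gave 2 to 45, 0 to 600, 11 to 173, 16 to 485, 0 to 82, 1 to 647 and 122 to 625 in the same order, and 0 to 6 genes shared by the ventilation contrasts; each highest value came without knockout SpV array 1. The cause was not tested. Arrays share only a replicate number: deviations of arrays with the same number correlated from -0.17 to 0.39 over 18 pairs, 6 of them over 0.1, and in 8 the array with the same number correlated best. A block on the number gave 4, 0, 36, 66, 0, 8 and 510, fewer genes for ventilation in wild type and more for averaged genotype. Signs reversed on the unscaled values: Tagln in averaged genotype was -0.18; at rest heat shock genes were -0.21, endoplasmic reticulum stress genes -0.20 and ciliated cell markers -0.048; after ventilation interferon genes were -0.061, cell cycle genes -0.40, club cell markers -0.12, ciliated cell markers -0.36, smooth muscle markers -0.54 and B cell markers -0.34; fibroblast markers in the interaction were -0.13; and in averaged genotype ciliated, smooth muscle and B cell markers were -0.21, -0.23 and -0.18. Each of these unscaled values lay above the median gene of its contrast. That gene had -0.48 at rest, -0.80 after ventilation, -0.33 in the interaction and -0.63 in averaged genotype. Read against those shifts, the directions were those of the main fit. Without knockout SpV array 1 fibroblast markers were 0.0017 at rest and -0.18 in the interaction, the ends of leave-out ranges that reach -0.91 and 0.68 without knockout SpV array 3. Of the named genes' values 11677 stayed on the same side of the threshold with the same sign, 414 gained and 684 lost a call and 1 reversed.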

Other observations

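All tests of the genes near Nfe2l2 in this part were chosen only after the result was seen. Jchain and Igha, picked after the values were seen, were high on 2 of the 3 knockout control arrays. Jchain, which joins IgA into dimers, had 6756.1 and 6801.9 on knockout SpV arrays 2 and 3, but 451.2 on array 1, 593.5 to 1215 in the knockout HVT group and 289.5 to 461.6 on the wild-type arrays. Igha followed with 6377, 5687.8 and 191 in the knockout SpV group and 198.4 to 450.4 on the wild-type arrays. Pigr, the epithelial receptor that carries such dimers, did not follow them, with 3031.4 on array 1 and 3151.1 and 3259 on arrays 2 and 3. At rest Jchain had a value of 2.85 ± 0.77 (n = 3 arrays per group, limma adjusted p = 0.131). Without array 1 it was 4.12 ± 0.27. The gene was picked for its high signal on arrays 2 and 3, so that fit is no test of it.

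Clock and growth factor genes were not called as lists. In wild-type lungs Per2, a clock gene that glucocorticoids can induce, had a value of 1.19 ± 0.29 with ventilation (limma adjusted p = 0.246) and passed when adjusted over the list alone, while the clock list had a median of 0.09 (camera adjusted p = 0.116). The stretch-linked growth factors had a median of 0.05 in wild type, with Ccn1 at 1.73 ± 0.59 and Hbegf at 1.54 ± 0.61 (0.99 without wild-type HVT array 1), and 0.19 when averaged over genotypes (camera adjusted p = 0.137 and 0.0814). Surfactant and other type II markers had -0.19 with ventilation of wild-type lungs and -0.11 by averaged genotype (camera adjusted p = 0.125 and 0.241), where 4 of 11 were higher. Macrophage and monocyte markers had -0.24 in averaged ventilation (camera adjusted p = 0.0828), hypoxia and glycolysis genes 0.05 with ventilation of wild-type lungs (camera adjusted p = 0.127), fat cell markers 0.72 by genotype after ventilation (camera adjusted p = 0.16), and the single thymus marker -0.29 with ventilation of wild-type lungs (camera adjusted p = 0.593). The fat cell value rests on knockout HVT array 2, which scored 2.13 against -0.25 and -0.51 on the other 2 arrays of its group, and which also had the highest heart and thymus scores, 1.14 and 0.80. Fabp4, a fatty acid carrier of fat cells, had 1.01 with all arrays and 0.0032 without that array. Coagulation genes in ventilated wild-type lungs had a median of -0.05 but a mean of 0.40, with 3 higher adjusted over the list alone, Thbs1 among them at 2.23 ± 0.73 (camera adjusted p = 0.116).

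Genes called by averaged genotype lie near Nfe2l2 more often than in most windows of 100 genes. Of the 100 measured genes nearest to it in the GRCm38.p6 annotation, 11 were called, 3 higher (Metap1d, Ttn and Mybpc3) and 8 lower (Tanc1, Dpp4, Scn7a, Cwc22, Ube2e3, Dnajc10, Tfpi and Aplnr). Of 7301 overlapping windows of that size 1.64% held as many, with a median of 3, and with heart muscle genes left out the share was 3.32% with 9 called, which argues against chance placement and against those muscle genes as the whole source for windows of this size. The shares were 3.06% for 50 genes, with 6 called, and 12.9% for 200, with 13 called, so the largest window does not set the region apart, and the windows are not independent. A segment of another strain kept around the targeted allele is a candidate explanation for Cwc22 at -2.16 ± 0.15 and Metap1d at 1.18 ± 0.18, and was not tested.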
